A study of Gallus gallus with 2 samples.

How the data were processed

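RNA-seq was measured in 2 libraries from hearts of chicken embryos (Gallus gallus), 1 from embryos given saline (the control library) and 1 from embryos given AAPH, 2,2-azobis(2-amidinopropane) dihydrochloride, a compound that releases free radicals (the AAPH library). Groups were taken from the labels' chemical entry. The labels do not say how many hearts went into each library or what sex the embryos were. Reads were handled with bcl2fastq, TopHat2 2.1.1, Cufflinks 2.2.1 and Cuffdiff, per the submitters' processing notes; the genome build and the annotation are not given in the sources used here. The deposited values are FPKM (fragments scaled by transcript length and by the library total), 1 value per assembled transcript and library, per the file headers. Each file lists the same 27335 transcripts of 14677 loci, and no transcript is at 0 in both. The tables hold no positions, transcript lengths, status flags or confidence intervals, so neither a filter on status nor a comparison using the authors' intervals was applied.

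Transcripts with the same gene name were summed, which gave 13011 names, 1553 of them Ensembl identifiers only. The 1968 transcripts without a name, which hold 18.2% of the control FPKM and 20.6% of the AAPH FPKM, were left out of the gene comparisons. Near-identical copies, such as members of the haemoglobin and histone families, can share reads, so their values are uncertain. For each gene the log2 ratio was log2((AAPH FPKM + 1)/(control FPKM + 1)). This scale understates the change of genes with low values. Genes with a mean FPKM of 1 or more entered (10106 genes), and a ratio of 2-fold or more was counted as higher or lower. With 1 library per group there is no spread between replicates, so no p-value, standard deviation or test of single genes was computed, and no difference has a replicate check.

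A total of 40 gene lists, 27 of pathways and 13 of markers of other cells or of the W chromosome, were written before the data were examined, as were the filter, the pseudocount, the fold thresholds, the rule for named genes and most of the other settings tried. A member was called higher or lower at a ratio of 1.5-fold (log2 0.585). For each list with 5 or more tested members, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart when its median lay below percentile 2.5 or above percentile 97.5 of these lists. This is a description of these 2 libraries. About 2 of the 39 lists would stand apart by chance if genes varied independently of each other. Genes of a list can vary together and some lists share members, so more may stand apart by chance. List symbols were matched to the file's names exactly, then regardless of case, then through synonyms in a RefSeq gene table (assembly GRCg7b). After the data were seen, 11 symbols were not matched through synonyms or letter case, because the match was another member of the gene family or ambiguous; NPPA was one of them and has no value here.

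Genes were named by 4 rules. They were the 15 genes with a symbol with the largest ratio each way; up to 4 members of each list that stood apart, in the direction of its median, and the member farthest the other way; the 3 members with the largest change in the antioxidant, NRF2, cardiac stress, sarcomere and extracellular matrix lists; and 12 reference genes, of which NPPA is not reported. Of the list members the rules named, 1 is not reported here. Genes named outside these rules were chosen after their values were seen, and the text says so. Membership of a chromosome and gene order along Z came from the same RefSeq table, because the files hold no positions; 88.0% of tested genes had a chromosome there. A second list of Z genes was written by hand from general knowledge after the data were seen. No coordinate of that table is used, because the authors' build is not known.

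Sequencing depth is not given by FPKM values, so the absolute depth of the libraries is unknown. The relative depth was read from 781 genes with 1 transcript and a control FPKM between 0.05 and 0.3. In 87.8% of them the ratio of the 2 libraries, divided by 1.05, was a ratio of integers up to 10 within a relative tolerance of 0.0002; with factors up to a few percent away, the median share was 0%. One fragment was thus worth 1.05 times as much FPKM in the AAPH library in these genes; very short transcripts were not tested. For the genes in the text with 1 transcript whose ratio was that of whole fragment numbers, at least 1 of them 10 or less, the smallest such pair (AAPH and control) is quoted with an exact binomial (Clopper-Pearson) 95% interval of the ratio. These intervals cover counting error only, and they are too wide where the true numbers are multiples of the pair.

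The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedure was tested on simulated data made from 9195 genes of the control library with a log2 noise SD of 0.2 and 200 genes changed 3-fold. Of the changed genes, 94% passed 2-fold in the right direction, and 0 unchanged genes did. A list shifted by 0.3 came out at percentile 100, and 4.25% of 400 unchanged lists stood apart. The noise was independent between genes and the unchanged lists were drawn at random. It had the same size at all abundances and was smaller than the SD over genes of the real log2 ratios (0.40). With such noise almost no unchanged gene could pass 2-fold, so the 0 does not measure false calls in the real data. These rates follow from that setting and do not cover genes that vary together. Alternatives were a pseudocount of 0.1 or 5, no filter or a mean FPKM of 5 or more, centring by the median of ratios, rescaling to TPM (each library to the same sum), rescaling in the same way without haemoglobin and mitochondrial-genome genes, a 1.5-fold threshold and each transcript on its own. Leaving out Z genes, leaving out small RNAs and genes listed at 0, the hand-written Z list, matched lists without ribosomal protein and mitochondrial-genome genes, using every synonym, TPM for the lists, the named genes, the spread and the Z comparison, and counts at 1.5-fold under the rescalings were added after the data were seen.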

Results

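Gene expression was compared between hearts of chicken embryos exposed to AAPH, a free radical generator, and hearts of embryos given saline, to ask how an oxidative environment alters cardiac transcripts during development. Eggs were incubated at 38 °C and 70% humidity. AAPH (2.6 µmol in 100 µL) was injected into the air chamber from Hamburger-Hamilton stage 35 and again on alternate days up to day 10, and hearts of surviving embryos were taken at stage 37 (day 11). Each group has 1 library, so every difference below lies between 2 libraries and has no replicate error. Summed FPKM was 1248089 in the control library and 1042407 in the AAPH library. In genes with low values, 1 fragment was worth 1.05 times as much FPKM in the AAPH library, and the absolute depth is unknown. Genes of the mitochondrial genome held 24.5% of FPKM in the control library and 23.4% in the AAPH library, and ribosomal protein genes held 11.2% and 9.10%.

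Most cardiac transcripts had similar values in the 2 libraries. PTH (parathyroid hormone) and TG (thyroglobulin, the precursor of thyroid hormone) had the largest ratios toward the AAPH library among protein genes with a symbol; genes under an Ensembl identifier alone were not ranked. PTH was at 0.435 FPKM in the control library and 19.3 in the AAPH library, and TG at 0.116 and 4.97. The co-chaperone gene DNAJC12 was at 30.5 and 83.8 FPKM, a log2 ratio of 1.43. On the other side, SDR42E2 was at 40.7 FPKM in the control library and 6.67 in the AAPH library (log2 ratio −2.44), GIF at 11.0 and 1.72 (−2.15), C14orf80 at 74.3 and 23.7 (−1.61) and CNP1 at 5.05 and 1.07 (−1.55).

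Of 10106 genes, 36 (0.356%) were 2-fold or more higher in the AAPH library and 79 (0.782%) were 2-fold or more lower, while 9433 genes (93.3%) lay within 1.5-fold. The median log2 ratio was 0.0039, with quartiles of −0.19 and 0.18. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.977 and Spearman's rho 0.974. Small RNAs made up 5 of the higher and 12 of the lower genes. Names with only an Ensembl identifier made up 15 and 33, and 6 of the higher genes were listed at 0 in the control library and 13 of the lower genes at 0 in the AAPH library. Among the genes the rule named, gga-mir-6585, U6atac and SNORA53 were listed at 0 in the control library, and gga-mir-6572, gga-mir-6542, SNORA65, SNORA31, SNORA1, SNORA21, SNORD94 and ST7-OT3_2 at 0 in the AAPH library. The non-coding RNAs uc_338 (log2 ratio 1.45), gga-mir-6652 (−2.44) and ACA64 (−1.94) had values in both. No fragment numbers were obtained for any of these RNAs, and a short RNA can reach a high FPKM from few fragments. Counting error was thus not excluded for them, also where a value of 0 is listed.

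Several genes with large ratios had low values in the control library. For PTH the smallest fragment numbers that give its ratio are 127 in the AAPH library and 3 in the control library, a ratio of 44.5 with a counting interval of 14.9 to 219. NRTN (neurturin, a ligand of the GDNF family) was at 0.254 and 2.14 FPKM, a ratio of 8.41 (counting interval 1.13 to 373) from 8 fragments and 1, and VSTM5 at 0.254 and 1.87, a ratio of 7.36 (counting interval 0.945 to 332) from 7 and 1. THAP1 (0.456 and 2.87 FPKM; counting interval 0.765 to 290 from 6 and 1), HS6ST3 (0.377 and 2.58; 1.55 to 62.4 from 13 and 2), ZDHHC20 (0.191 and 3.97; 10.7 to 46.2 from 178 and 9) and DNASE1L3 (1.009 and 3.78) also had low control values. If VSTM5 and THAP1 rest on these smallest numbers, their directions are within counting error. KIAA1328 and SOUL had log2 ratios of 1.30 and 1.20, and TM4SF1 was lower, at 2.14 and 0.225 FPKM (ratio 0.105, counting interval 0.002 to 0.739 from 1 and 10).

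**Figure D1:**
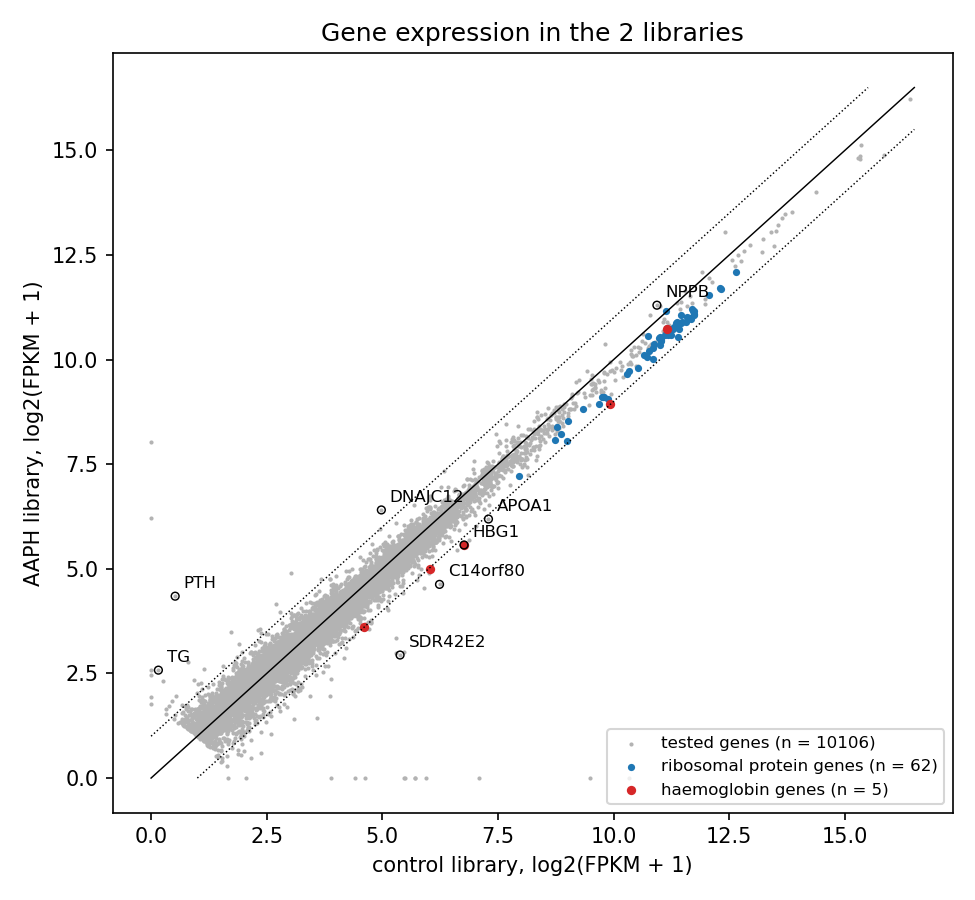
Each point is 1 of 10106 genes, with log2(FPKM + 1) in the control library on the x axis and in the AAPH library on the y axis; the solid line marks equal values and the dotted lines 2-fold. Most points lie along the line, PTH and TG lie above it, and 61 of the 62 ribosomal protein genes (blue) and the 5 haemoglobin genes (red) lie below it.

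The share of higher among the 2-fold genes depended on the scaling. It was 31.3% as deposited (36 higher and 79 lower), 69.0% after rescaling to TPM (80 and 36) and 69.1% after rescaling without haemoglobin and mitochondrial-genome genes (96 and 43). Rescaling to TPM moved the median of all genes by 0.23 and the other rescaling by 0.21, while centring by the median of ratios moved it by −0.003. Counts at 1.5-fold depended on it too, with 276 genes higher and 397 lower as deposited, 849 and 162 after rescaling to TPM and 862 and 185 after the other rescaling. Genes of higher abundance had lower ratios, with medians of 0.06 at a mean FPKM of 1 to 3, −0.07 at 30 to 100, −0.15 at 100 to 1000 and −0.45 for the 122 genes at 1000 or more. Without ribosomal protein and mitochondrial-genome genes, 60 of the 122 remained, with a median of −0.30. The gene lists are therefore described against random lists matched on abundance.

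Genes of the antioxidant defence, whose products remove reactive oxygen species, did not differ from matched genes as a group. Of 26 tested antioxidant enzymes, 1 was higher at 1.5-fold and 0 lower, with a median log2 ratio of −0.16 (percentile 15.7). Of 33 NRF2 targets and glutathione genes, 1 was higher and 2 lower (median 0.03, percentile 80.5). Catalase (CAT, 15.6 and 15.9 FPKM), haem oxygenase 1 (HMOX1, 10.4 and 10.6), the superoxide dismutases SOD1 (253 and 239) and SOD2 (329 and 313) and NFE2L2, the gene of NRF2 itself (23.6 and 26.4), were within 1.5-fold. Higher members were thioredoxin reductase TXNRD1, at 2.51 and 4.32 FPKM (log2 ratio 0.60), and GCLC, the catalytic subunit of the first enzyme of glutathione synthesis, at 9.77 and 17.6 (0.79). The ferritin heavy chain FTH1 was lower, at 4032 and 2552 FPKM (−0.66), as was SQSTM1, an autophagy receptor (−0.59). Glutathione peroxidase GPX1 (−0.57) and metallothionein MT4 (−0.46) stayed within 1.5-fold. The 10 tested oxidant-producing enzymes had a median of −0.09 (percentile 17.7). Under both rescalings 3 NRF2 targets and glutathione genes were higher and 0 lower, so that FTH1 and SQSTM1 came within 1.5-fold; the medians of the antioxidant and the oxidant-producing lists and the ratios of SOD1 and SOD2 lay above 0, with no list past the percentile limits.

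The lists of calcium handling, cardiac stress and sarcomere genes had higher medians than genes of like abundance in the AAPH library. Cardiac transcription factors did not stand apart, and as deposited 16 of the 31 sarcomere ratios lay below 0. Genes of calcium handling and ion channels had a median log2 ratio of 0.14 (32 genes, percentile 99.9), cardiac stress genes 0.13 (21 genes, percentile 99.8) and sarcomere genes −0.01 against −0.17 in matched lists (31 genes, percentile 99.5, and 98.5 with ribosomal protein and mitochondrial-genome genes left out of the matched lists). Among stress genes, ANKRD1, a stretch-responsive nuclear protein of cardiomyocytes, was at 10.8 and 20.2 FPKM (log2 ratio 0.84) and CTGF, a matricellular growth factor, at 38.1 and 67.6 (0.81). The natriuretic peptide gene NPPB was at 1957 and 2518 (0.36), bFGF had a ratio of 0.36, and MYH7 was lower, at 215 and 127 (−0.76). At 1.5-fold, 2 stress genes were higher, 1 lower and 18 neither, and under both rescalings 3 were higher and 0 lower. Erythroid, neuronal, liver and fibroblast markers lay below their matched lists in the same comparison (percentiles 0.29, 0.29, 0.61 and 1.6), so a difference in tissue make-up was not separated from a change within muscle cells.

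Of the 32 calcium handling genes, 1 was higher at 1.5-fold and 0 lower. This gene was the calcium/calmodulin-dependent kinase CAMK2D, at 14.3 and 22.8 FPKM (log2 ratio 0.64). The junctophilin JPH2 (0.54), the potassium channel KCNJ3 (0.48) and the connexin GJA1 (0.44) followed, and the beta-adrenergic receptor ADRB1 lay at −0.18. Under both rescalings 5 of the 32 were higher, these 4 among them, and all 32 ratios lay above 0. In the sarcomere list TMOD1, which caps thin filaments, was higher, at 204 and 352 FPKM (0.78), while MYH7 and the myosin chaperone UNC45B (125 and 81.4 FPKM, −0.62) were lower and 28 were neither. MYL4 (−0.36) and MYBPC3 (−0.35) followed, and ACTC1 (2629 and 2598 FPKM, −0.02) and TNNT2 (5989 and 5342, −0.16) were close. The 31 tested cardiac transcription factors had a median of −0.01 (percentile 54.8). Under both rescalings the sarcomere and transcription factor medians and the ratios of ADRB1, ACTC1 and TNNT2 lay above 0, and 2 sarcomere genes were higher and 0 lower, with MYH7 and UNC45B within 1.5-fold.

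Genes of the extracellular matrix were higher in the AAPH library than genes of like abundance, with a median log2 ratio of 0.16 in 58 genes against −0.04 in matched lists (percentile 99.99), and 41 of the 58 had ratios above 0. At 1.5-fold, 0 genes were higher as deposited and 15 under each rescaling, where 52 of the 58 had ratios above 0 and the median was 0.39 (TPM) and 0.37. The elastic fibre protein FBLN5 was at 9.71 and 14.96 FPKM (log2 ratio 0.58), the metalloproteinase inhibitor TIMP3 at 6.84 and 10.6 (0.57), the laminin LAMB1 at 27.9 and 40.5 (0.52) and the lysyl oxidase LOXL2 at 3.16 and 4.97 (0.52). Tenascin C (TNC) was the 1 lower member, at 5.18 and 2.65 FPKM (−0.76), and came within 1.5-fold after rescaling to TPM. Markers of fibroblasts and epicardium, cells that make matrix, lay on the other side of their matched lists (median −0.18, percentile 1.6). Under both rescalings their median was above 0, at percentiles 2.02 and 2.16. The 2 lists share members as written, OGN, COL1A1 and DCN among them, so they are not separate sets of genes. The relation of the 2 lists was not tested.

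Cell cycle and heat shock genes also stood above matched lists. Here too, a difference in tissue make-up was not separated from a change within cells. The cell cycle list had a median of 0.08 in 66 genes (percentile 99.6), with 2 genes higher, 1 lower and 63 neither. Cyclin D2 (CCND2) was at 6.10 and 12.1 FPKM (log2 ratio 0.89) and ECT2, a regulator of cytokinesis, at 7.16 and 11.5 (0.62). PLK4 (0.54) and CENPI (0.46) were within 1.5-fold, and the replication factor GINS1 was lower (−0.61). Under both rescalings 5 were higher and 0 lower, with PLK4 and CENPI past 1.5-fold and GINS1 within it. The heat shock list had a median of 0.04 in 35 genes (percentile 99.0), with 1 gene higher and 34 neither. HSPB3, a small heat shock protein of muscle, was at 64.3 and 106 FPKM (0.71), DNAJB5 at 9.6 and 14.04 (0.51), the collagen chaperone SERPINH1 at 187 and 255 (0.45), HSP90AA1 at 324 and 426 (0.39) and HSPB1 at 2137 and 1656 (−0.37). Under both rescalings 6 of the 35 were higher and 0 lower.

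**Figure D2:**
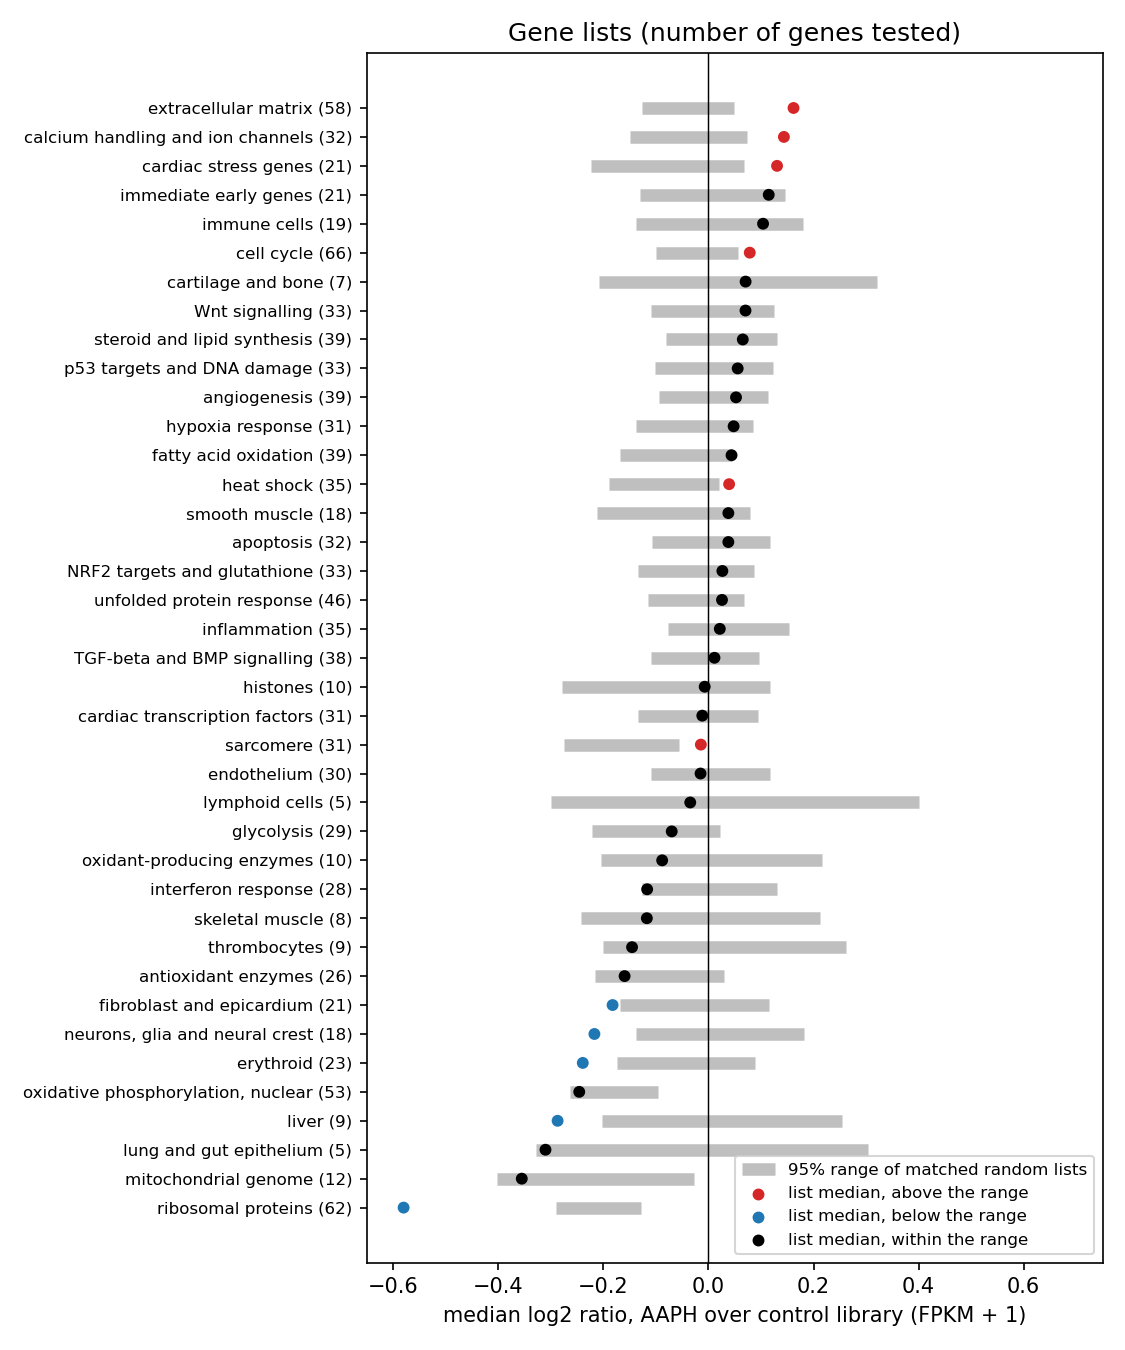
Points are the median log2 ratios of 39 gene lists, AAPH over control library, with the number of tested genes in parentheses; grey bars span the central 95% of 10000 random lists matched on mean expression. The 6 lists in red lie above their bars and the 5 in blue below them, with ribosomal proteins farthest at −0.58. Rescaling to TPM moves the median of all genes by 0.23, and some medians below 0 then lie above it.

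Ribosomal protein genes were lower in the AAPH library nearly as a whole. Of 62 tested genes, 61 had ratios below 0, 28 were lower at 1.5-fold and 0 higher, with a median log2 ratio of −0.58 against −0.21 in matched lists (percentile 0). RPS21 was at 505 and 263 FPKM (−0.94), RPL37A at 2686 and 1479 (−0.86), RPS12 at 1843 and 1039 (−0.83) and RPL35 at 935 and 530 (−0.82). RPS6, which lies on the Z chromosome, was at 2255 and 2281 (0.02). Under both rescalings the median stayed below 0, at −0.32 and −0.34, as did 60 of the 62 ratios, but 2 (TPM) and 3 genes were lower at 1.5-fold in place of 28.

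Genes of the mitochondrial respiratory chain had medians below 0 as deposited, but neither of their 2 lists stood apart. For the nuclear list, this depended on the genes it was matched to. All 12 tested genes of the mitochondrial genome had ratios below 0, with a median of −0.36 (percentile 6.5), from ND3 at 11311 and 6718 FPKM (−0.75) and ND6 at 9483 and 6059 (−0.65) to ATP8 at 86941 and 76429 (−0.19). Under both rescalings 9 of the 12 lay below 0 and 3 above, among them ATP8 (0.07 after rescaling to TPM). Of 53 nuclear genes of the chain, 41 had ratios below 0 and 0 were past 1.5-fold either way, with a median of −0.25 (percentile 7.04, and 0.49 with ribosomal protein and mitochondrial-genome genes left out of the matched lists), among them NDUFB4 (−0.51) and COX5A (−0.49). Toward the other side lay ATP5A1 (0.55), NDUFS4 (0.49) and COX7C (0.28), which are Z-linked. These genes were chosen after their values were seen. Under both rescalings 3 of the 53 were higher at 1.5-fold. The nuclear median was 0.01 after rescaling to TPM (31 of the 53 ratios above 0 and 22 below), while the mitochondrial-genome median was −0.10. The glycolysis list lay at −0.07 (percentile 66.8, above 0 under both rescalings), with GAPDH at 11628 and 8653 FPKM (−0.43).

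**Figure D3:**
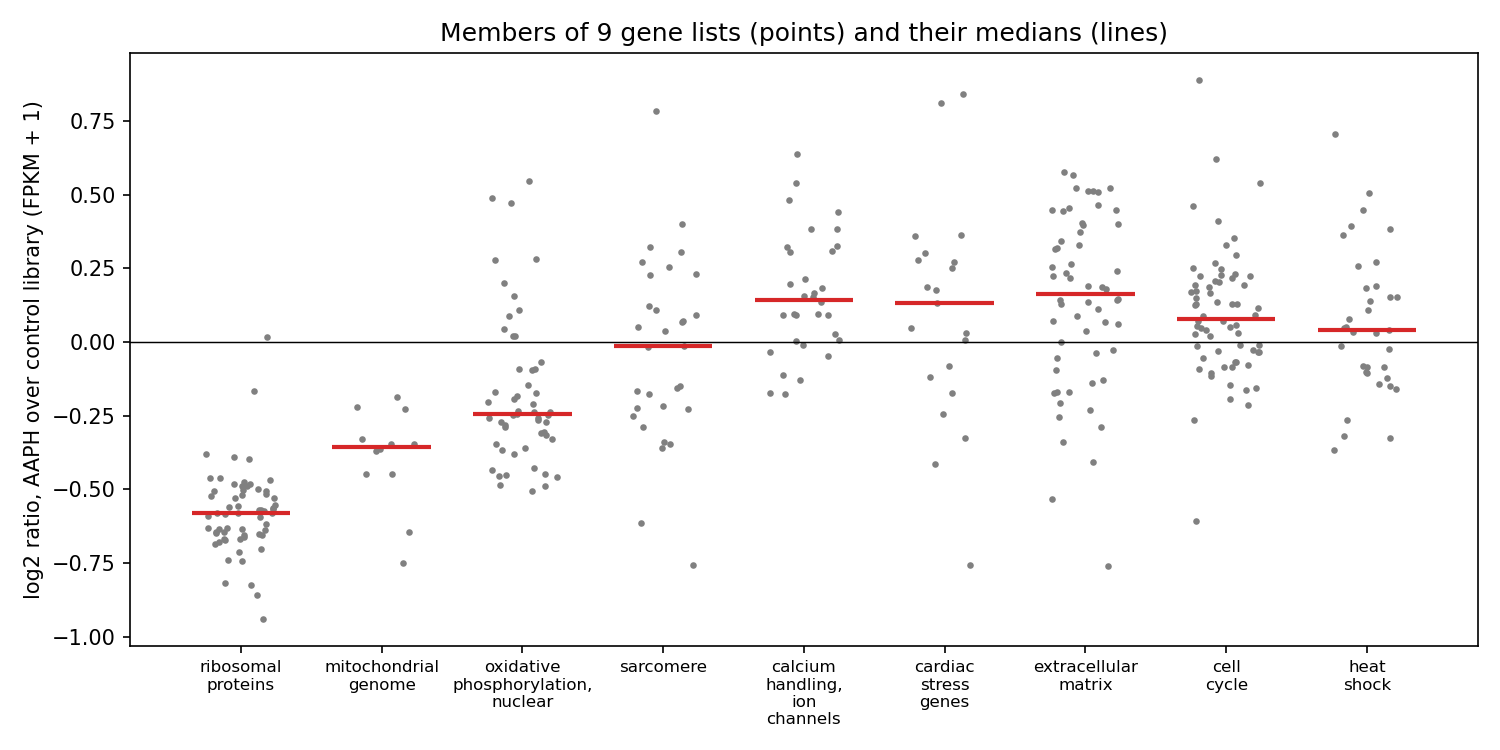
Points are the log2 ratios, AAPH over control library, of the tested members of 9 gene lists, and red lines are the list medians. Ribosomal protein genes centre at −0.58 and mitochondrial-genome genes at −0.36, while extracellular matrix genes centre at 0.16; after rescaling to TPM the nuclear oxidative phosphorylation and sarcomere medians lie above 0.

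The other pathway lists did not stand apart. Fatty acid oxidation (39 genes) had a median of 0.04 at percentile 97.4. Without Z genes the median was −0.006 (percentile 85.4), and at a mean FPKM of 5 or more it was also −0.006 (89.7). Its highest members included PLIN2 (log2 ratio 0.75), LPL (0.52) and ACAA2 (0.41), all on Z and chosen after their values were seen. Immediate early genes (21) lay at 0.11 (percentile 93.0), hypoxia genes (31) at 0.05 (90.3), and interferon response genes (28) at −0.12 (3.33; median 0.09 and percentile 2.47 after rescaling to TPM). Percentiles were 84.6 for the unfolded protein response, 83.1 for Wnt signalling, 77.2 for angiogenesis, 75.8 for p53 targets and DNA damage, 74.2 for steroid and lipid synthesis and 73.8 for histones. They were 68.8 for apoptosis, 61.1 for TGF-beta and BMP signalling and 40.2 for inflammation.

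Markers of several other cell types were lower in the AAPH library than genes of like abundance. Erythroid genes had a median of −0.24 in 23 genes (percentile 0.29), with 5 lower at 1.5-fold and 1 higher. The haemoglobin genes HBG1 (108 and 46.5 FPKM, log2 ratio −1.20), HBE (64.2 and 30.8, −1.03), HBZ (23.4 and 11.2, −1.0) and HBE1 (965 and 492, −0.97) led, and UROS, of haem synthesis, lay at 0.59. The FPKM of HBG1, HBG2, HBE, HBE1 and HBZ summed to 3427 in the control library and 2275 in the AAPH library. HBA1, HBAA and HBAD of the list had no value under these names, so the sum does not cover all haemoglobin. With ALAS1 counted in place of ALAS2, the list lay at percentile 2.45. After rescaling to TPM the list of 23 genes had a median of 0.01, with 4 lower and 1 higher.

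Genes of neurons, glia and neural crest had a median of −0.22 in 18 genes (percentile 0.29), with 5 lower and 0 higher, and percentile 6.86 at a mean FPKM of 5 or more. The neurofilament NEFM was at 2.91 and 1.14 FPKM (log2 ratio −0.87), GAP43 at 5.28 and 2.78 (−0.73; ratio 0.526, counting interval 0.009 to 10.1 if it rests on the smallest numbers, 1 and 2, so counting error is not excluded) and STMN2 at 14.8 and 8.63 (−0.72), while neuropeptide Y (NPY) lay at 0.57. Rescaled, the median was −0.04 (TPM) and −0.06, with 2 lower, 1 higher and 8 of 18 ratios above 0. Liver genes had a median of −0.29 in 9 genes (percentile 0.61), with 2 lower at 1.5-fold, 0 higher and 4 of the 9 ratios above 0. The lower ones were the apolipoprotein APOA1, at 156 and 72.0 FPKM (−1.10), and HPD, at 3.93 and 2.29 (−0.59). The steroid and lipid synthesis list also holds APOA1. SERPINC1 (−0.32) and HPX (−0.30) followed, and F10 lay at 0.41. Rescaled, the liver median was −0.05 (TPM) and −0.07, with 1 lower. Fibroblast and epicardium genes had a median of −0.18 in 21 genes (percentile 1.6), with the epicardial factor WT1 at 9.14 and 5.62 FPKM (−0.62), KRT19 (−0.44), cdermo-1 (−0.41) and OGN (−0.41) lower and dermatopontin (DPT) at 0.64. Under both rescalings the fibroblast median was above 0 and WT1 within 1.5-fold.

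Markers of smooth muscle (18 genes, percentile 91.6), immune cells (19 genes, 83.7), cartilage and bone (7 genes, 52.7), endothelium (30 genes, 33.5), lymphoid cells (5 genes, 27.9), skeletal muscle (8 genes, 16.0), thrombocytes (9 genes, 5.64) and lung and gut epithelium (5 genes, 3.20) did not stand apart. Of the W-linked list, 0 genes were found among the names, so transcripts of the female-specific chromosome were not analysed here.

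Z-linked genes were higher in the AAPH library as a chromosome. Birds are ZZ in males and ZW in females, and Z genes are not fully dosage compensated, so this comparison was planned as a check on the sexes behind the 2 libraries. The 408 Z genes had a median log2 ratio of 0.30 and the 8470 autosomal genes −0.0006, a difference of 0.31 (1.24-fold; 0.27 to 0.32 over resampled genes, which is not an error between replicates). The Z median lay at percentile 100 of matched lists, whose upper limit was 0.05. Of the Z genes, 84.3% lay above the autosomal median, and the differences in 4 consecutive equal parts of the Z genes in gene order were 0.31, 0.31, 0.29 and 0.30. The next highest of the 28 chromosomes with 50 or more tested genes had a median of 0.04 and the lowest −0.15. Chromosomes 2 and 1 also lay above the upper percentile limit of their matched lists (99.8 and 99.7). Below the lower limit lay chromosomes 14, 21, 23 and 25 (2.47, 1.64, 1.31 and 0.03). Sets of genes that were not chosen by function thus stood apart as well, by smaller medians than Z, and the reason was not tested.

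Many of the higher genes were Z-linked. On Z lay 62 of the 217 genes (28.6%) that were 1.5-fold or more higher and had a chromosome, 3 of the 269 lower ones (1.12%) and 4.59% of all tested genes. After rescaling to TPM these were 154 of 728 (21.2%) and 1 of 95 (1.05%). At 2-fold, 5 of 17 higher genes were on Z, namely THAP1, KIAA1328, LMBRD2 (log2 ratio 1.08; ratio 4.03, counting interval 1.59 to 12.1 from 23 and 6), ZFAND5 (1.07) and DMGDH (2.62 and 6.43 FPKM), the last 3 chosen after their values were seen. TMOD1, HSPB3 and DNAJB5 are Z-linked as well. Leaving out the Z genes, the matrix, calcium handling, stress, sarcomere, cell cycle and heat shock lists still stood above matched lists. Of their tested members, 4 matrix, 3 heat shock and 1 sarcomere gene lie on Z. The calcium handling, stress and cell cycle lists hold 0, so for them this step changed only the matched lists and tested nothing.

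**Figure D4:**
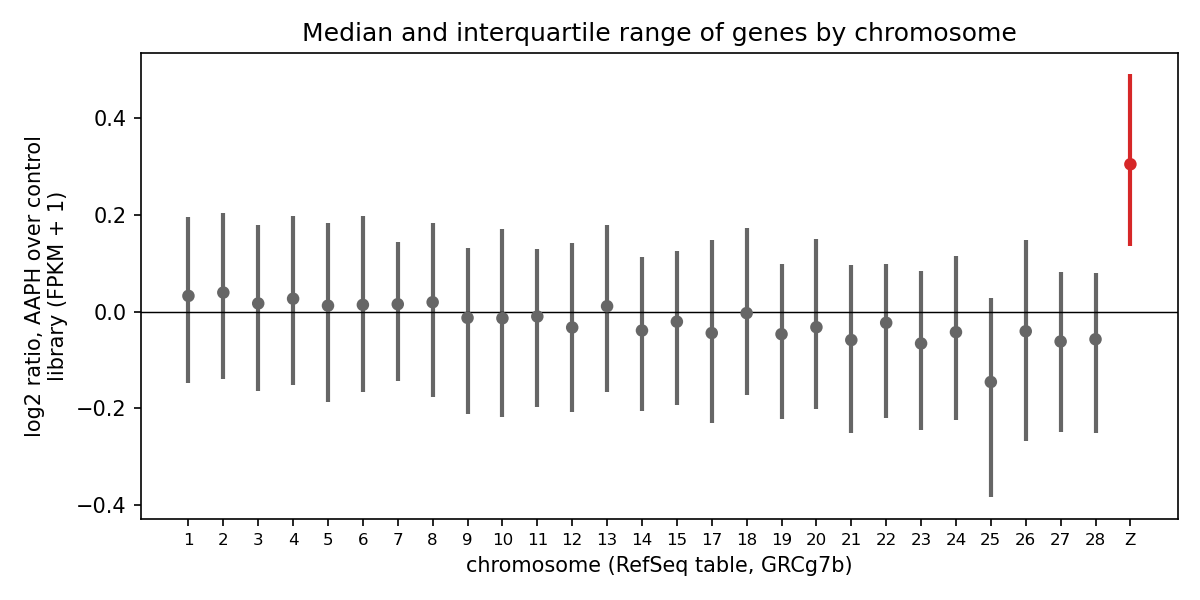
Points are the median log2 ratios, AAPH over control library, of the tested genes of each chromosome with 50 or more of them, and lines span the interquartile range. The Z chromosome (red) has a median of 0.30, and the other 27 lie between −0.15 and 0.04.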

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

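Tests of the thyroid and parathyroid genes were chosen only after PTH and TG had been seen among the largest ratios, and no result of this part was planned.

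Transcripts without a gene name were outside the gene comparisons. Of 1632 loci with such transcripts and a mean FPKM of 1 or more, 71 were 2-fold or more higher in the AAPH library than in the control library and 154 were 2-fold or more lower, 4.35% and 9.44% against 0.356% and 0.782% of named genes. The median log2 ratio of the tested loci was −0.15. The locus with the highest mean, XLOC_015852, was at 69423 and 84783 FPKM. Other loci with high means lay on both sides, such as XLOC_002450 at 11401 and 655 FPKM (log2 ratio −4.12) and XLOC_007834 at 24275 and 32776 (0.43). No fragment numbers are given for these loci, and a short transcript can reach a high FPKM from few fragments, so counting error was not excluded for them.

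Markers of thyroid follicle and parathyroid cells were above the control library at values below the FPKM minimum. IYD, an iodide-recycling enzyme of the thyroid, was at 0.033 FPKM in the control library and 0.897 in the AAPH library, GCM2, the parathyroid transcription factor, at 0.152 and 0.798, and the calcium receptor CASR at 0.270 and 0.633. TSHR (0.111 FPKM) and NKX2-1 (0.147), which the lung list also holds, were listed at 0 in the control library.

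PTH and TG, at 19.3 and 4.97 FPKM in the AAPH library, are genes of glands that lie beside the great vessels of the heart. For PTH the values argue against counting error, since the lower 95% bound of the PTH ratio was 14.9. A small piece of thyroid or parathyroid tissue in the AAPH library may be the source. In a list of 14, 5 of the 5 other genes with a value above 0 were higher there. TSHR and NKX2-1 were counted only through their AAPH values, so their direction was fixed and adds no support. All 5 of these genes lie below the FPKM minimum, and fragment numbers were obtained only for IYD and GCM2. The smallest numbers for IYD are 26 and 1, a ratio of 27.3 (counting interval 4.49 to 1120). For GCM2 they are 5 and 1, a ratio of 5.26 (0.588 to 249). If GCM2 rests on these numbers, its direction is within counting error. No interval was computed for CASR, TSHR and NKX2-1. CASR and NKX2-1 are not exclusive to these glands, and the heart can express CASR. A response of the heart to AAPH was not tested and stays open, since 1 library per group cannot part the dissection from the treatment.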

How the results depend on the processing

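With 1 library per group, no setting gives an error between embryos, and unknown absolute depth limits what low genes show. No paired analysis was possible because there is 1 library per group, and the alternative with the authors' intervals was not run. Settings named in the processing account as added were chosen after seeing the data. Genes 2-fold higher numbered 36 and lower 79. At a pseudocount of 0.1 they numbered 106 and 162, at 5, 8 and 25, and at a mean FPKM of 5 or more, 14 and 52, where fewer genes are tested. After rescaling to TPM they numbered 80 and 36, and without haemoglobin and mitochondrial-genome genes 96 and 43. By construction a 1.5-fold threshold gave more (276 and 397). Each transcript on its own gave 1428 and 1329. Without a filter there were 51 and 95, centred 35 and 81, without Z genes 31 and 79, and without small RNAs and genes listed at 0, 28 and 62. The interquartile range of the ratios (0.371) was 0.415 at a pseudocount of 0.1, 0.255 at 5, 0.353 at a mean FPKM of 5 or more and 0.358 after rescaling to TPM. The Z difference (0.31) was 0.34 at a pseudocount of 0.1 and 0.20 at 5, and between 0.28 and 0.32 in the other settings. Apart from what the construction shows, the cause was not tested. Of 345 list results under alternatives, 340 kept their side of the percentile limits. Centring and the rescalings shift a list and its matched lists nearly alike, so few changes could come from them. Neurons lost the call at a mean FPKM of 5 or more (percentile 6.86), where immediate early genes (99.4) and interferon genes (1.58) gained it, as interferon genes did after rescaling to TPM (2.47) and the nuclear respiratory chain without ribosomal protein and mitochondrial-genome genes (0.49). No named gene past 1.5-fold changed sign, and under these settings none could. A pseudocount or a filter keeps the sign, and centring and the rescalings shift ratios by less than the 1.5-fold limit.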

Other observations

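The tests of explanations in this part were chosen only after the values were seen, while the Z comparison itself was planned.

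Members of lists that did not stand apart had ratios on both sides, and the genes here were chosen after their values were seen. Among Wnt genes, WNT2B was at 10.9 FPKM in the control library and 4.48 in the AAPH library (log2 ratio −1.11), the secreted antagonist SFRP5 had a log2 ratio of −0.80 (ratio 0.430, counting interval 0.174 to 0.972 from 9 and 22) and RSPO3, which amplifies Wnt signals, was at 6.11 and 3.50 (−0.66). These are the 3 lower members at 1.5-fold; 0 were higher, 18 of the 33 had ratios above 0, the median was 0.07, and under both rescalings 2 were lower and 1 higher. In the TGF-beta and BMP list, BMP2 (5.36 and 2.61 FPKM, −0.82) and GDF10 (−0.79) were lower, while the receptor BMPR1B (0.67 and 2.29 FPKM, 0.98), the signal transducer SMAD3 (0.66) and BMP-10, a ligand of trabecular heart muscle (19.3 and 30.7 FPKM, 0.65), were higher. The list as a whole had 3 genes higher and 2 lower at 1.5-fold, and 5 and 1 after rescaling to TPM.

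The interleukin 33 receptor IL1RL1 was at 23.6 and 11.9 FPKM (log2 ratio −0.93), and the macrophage genes CTSS (−0.85) and C1QB (−0.62) were lower while DMB2 (0.83) was higher. The immune cell list as a whole had 1 gene higher and 2 lower at 1.5-fold, with 10 of 19 ratios above 0. Under both rescalings 2 were higher and 1 lower. The stress-induced transcription factor ATF3 was at 5.59 and 9.90 FPKM (0.73), TRIB1 at 1.92 and 4.38 (0.88; ratio 2.28, counting interval 0.808 to 7.31 from 13 and 6, so counting error is not excluded) and the Z-linked NFIL3 at 4.57 and 9.89 (0.97). The oxidase NOX4, which makes hydrogen peroxide, was at 0.67 and 1.53 FPKM (0.60), and CYBA, a partner subunit of such oxidases, at 47.5 and 32.8 (−0.52).

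Z-linked genes were 0.31 higher than autosomal genes on the log2 scale. The values argue against abundance as the reason, as matched lists reached 0.0506 at their upper percentile limit. A larger share of male hearts in the AAPH library is a candidate explanation, as 84.3% of Z genes lay above the autosomal median. Also, 4 equal parts of the chromosome in gene order differed little (0.29 to 0.31). The list of Z genes written by hand gave 0.31. It checks the chromosome labels only, since 90 of its 94 tested genes are on Z in the RefSeq table. A response of Z genes to AAPH (0.305) cannot be told apart from a larger share of male hearts. The reason is that 1 library per group joins the sex of the hearts to the treatment, and no W-linked gene was analysed here. If more male hearts survived AAPH, the design would show the same values.

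Ribosomal protein genes had a median of −0.58. Other genes of like abundance had a median of −0.23 (matched lists from −0.29 to −0.16), so lower values of all abundant genes do not reach it. Fewer red blood cells as the whole cause would need their genes to fall at least as far. The 23 erythroid genes had a median of −0.24 (quartiles −0.47 and 0.11), short of that, and the 18 other than haemoglobins −0.058 (quartiles −0.28 and 0.13). Of the 23, 5 fell as far as the ribosomal median, namely HBG1, HBE, HBZ, HBE1 and the transferrin receptor TFRC (66.3 and 38.6 FPKM, −0.77), while the most abundant, HBG2 (2267 and 1695 FPKM), lay at −0.42, TSPO2 (373 and 304) at −0.29, RHAG at 0.12 and HEMGN, on Z, at 0.13; members outside the naming rules were chosen after their values were seen. Several of the 23, such as TFRC, are not exclusive to red blood cells, so the list median cannot exclude fewer of these cells. The haemoglobin genes HBG1, HBE, HBZ and HBE1 fell farther than the ribosomal median, and HBG2 less far. The summed FPKM of these haemoglobin genes was 3427 in the control library and 2275 in the AAPH library. It leaves out HBA1, HBAA and HBAD, which had no value under these names. Fewer red blood cells may account for part of the haemoglobin and ribosomal values, and whether they account for more was not settled. A bias against short transcripts cannot be told apart from lower ribosomal expression, because the lengths were not used here; the nuclear respiratory chain list, also of many short transcripts, lay at −0.25, below matched lists only with ribosomal protein and mitochondrial-genome genes left out of them (percentile 0.49). A response to AAPH stays open and untested.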
